A study of Mus musculus with 6 samples.

How the data were processed

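RNA was sequenced from macrophages that had been induced with M-CSF from mouse bone marrow, in 3 Lamtor5 knockdown and 3 WT libraries. Per the labels' protocols, total RNA was extracted with a column kit and the libraries were made with a SMARTER mRNA-Seq kit. The genome build was GRCm38 (mm10), per the submitters' processing notes. Per the file headers of the trimming logs, the authors removed adapters with cutadapt 1.9 in paired-end mode, with an overlap of at least 5 bases and a minimum read length of 100 bases; reads were 141 nt long. The aligner, the counting program, the annotation release and whether counting used strand are not given in the sources used here. The groups come from the genotype label. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

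The authors deposited a single table of 55401 genes with a count column and an FPKM column for each library, per the file headers. The count columns hold whole numbers, but they are estimated counts made by the authors, not a tally of reads. Each sums to 2.95 to 3.01 per read pair kept. Low values pile up on 4 (15.9% of values from 1 to 30 in genes with a single transcript, against 3.23% on 5). The values were already whole and were not rounded. For 9186 genes with over 500 counts in each library, the ratio of count to deposited FPKM was a constant per library times a constant per gene (largest SD of the log2 ratio over genes within a library 0.0007). The authors' FPKM is listed at 0.0001 where the count is 0. Of the table's gene identifiers, 55141 were found in GENCODE M21, and 93.8% of the table had the same coordinates there; coordinates printed here are those of the table. Every gene had a name in the table, and 120 names belonged to more than 1 identifier, for which a list used the identifier with the most counts.

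The depth was 26.0 to 28.0 M read pairs and 75.8 to 83.2 M estimated counts per library. Since the counts exceed the read pairs, no binomial interval was made from them.

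The main test was edgeR 4.0.16 (R 4.3.3) on the estimated counts: genes kept by filterByExpr (minimum count 10), TMM scaling, quasi-likelihood fit and test with package defaults, group as the only term, and Benjamini-Hochberg adjustment over 18164 genes with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Deposited FPKM values are printed as mean ± SD for n = 3. Gene lists were tested with camera (limma 3.58.1) on edgeR's z-scores with a preset correlation of 0.01, adjusted over the 37 lists with at least 3 tested genes (a list of 5 sex-linked genes had 1), and again with an estimated correlation and with fry. Library values were compared with exact permutation tests (scipy 1.17.1), 7 measures as a family. Library correlations and principal components used log2 counts per M of the tested genes.

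Before the data were examined, the design, the 38 gene lists, the rule for named genes and the other settings listed below were fixed. The design planned limma on log2(FPKM + 1) unless the table held counts, which it did, so the count test became the main test as written. The rule named Lamtor and v-ATPase genes that pass; the 12 genes higher and 12 lower with the largest log2 fold change among genes past the threshold with a mean of at least 5 FPKM in the higher group, groups that do not overlap and no predicted-gene name; and up to 4 members of each list with the smallest p. Lyz2, Lyz1, Lamtor1 to Lamtor4, Igf1, the progenitor markers Elane, Cd34, Myb, Gfi1, Ms4a3 and Fcnb, and genes described as under the filter were added after their values were seen.

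On simulated counts for this comparison (17528 genes tested, 200 changed, and a set of 40 shifted for camera), edgeR recovered 2 of 67 genes changed 1.5-fold, 17 of 67 changed 2-fold and 30 of 66 changed 3-fold, with 55 calls in all, of which 1 was a gene of the shifted set and 5 were false. Camera on these simulated counts returned 7.68e-14 for a shifted set and 0.711 for an unshifted set. The simulated genes were drawn independently of each other. The simulation thus cannot test the preset correlation on lists whose genes vary together, such as cell cycle (estimated correlation 0.93).

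The alternatives were RLE size factors, DESeq2 1.42.0, no count filter, limma on log2(FPKM + 1) with a minimum mean of 1 FPKM under other pseudocounts, filters, scalings, weights and empirical Bayes settings, the replicate number as a block, and each library left out in turn; for an alternative, a change of sign was counted only where the gene or list passed in at least 1 of both fits. A test on recovered whole reads was not run because the table holds estimated counts. Some named genes overlap another gene in the table (Kif4 and Pdzd11, Ccna2 and Exosc9, Pclaf and Trip4, Ube2c and Tnnc2, Kif20a and Cdc23, Htra1 and Fgfr2, Atp6v1h and Rgs20, Atp6v1e1 and Slc25a18, Stab1 and Nt5dc2, Fdft1 and Ctsb, Myd88 and Acaa1a); since the use of strand is not stated, reads of such pairs may have been mixed.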

Results

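Gene expression was measured by RNA sequencing in bone marrow-derived macrophages, the cells that grow out of bone marrow cultured with M-CSF (the macrophage growth factor). There were 6 mouse libraries, 3 from a Lamtor5 knockdown and 3 from wild type (WT). Lamtor5, also called HBXIP, is a subunit of Ragulator, the complex that anchors the Rag GTPases and mTORC1 to the lysosome surface. The study's description marks the mutant mice with LysM, the promoter of the lysozyme gene Lyz2 that is used to express Cre recombinase in myeloid cells. Between 26.0 and 28.0 M (1e6) read pairs were sequenced per library, and the deposited estimated counts summed to 81.3, 75.8 and 79.7 M in knockdown replicates 1 to 3 and to 82.5, 83.2 and 83.0 M in WT replicates 1 to 3. The 6 libraries correlated at Pearson r 0.961 to 0.967 within the knockdown, 0.968 to 0.974 within WT and 0.935 to 0.959 between the groups (across genes, which are not independent replicates). The first principal component, with 42.9% of the variance, separated the 2 groups.

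The targeted gene was measured first. Lamtor5 (ENSMUSG00000087260, GRCm38 chromosome 3, 107278858 to 107284082, plus strand, 4 exons in its main transcript, no overlapping gene) had 25.8 ± 1.21 FPKM in the knockdown and 55.5 ± 0.924 FPKM in WT (mean ± SD, n = 3), that is 46.5% of the WT level. The single knockdown libraries held 25.5, 27.1 and 24.8 FPKM and the WT libraries 55.9, 54.5 and 56.2, so the groups did not overlap (exact permutation test, two-sided, p = 0.1, the smallest value that 3 against 3 can give). In edgeR's quasi-likelihood test the log2 fold change was -1.06 (SE 0.078, Benjamini-Hochberg adjusted p = 0.00963), and -1.09 with adjusted p = 0.0616 without WT replicate 2. The other Ragulator subunits did not pass the test: the log2 fold changes were 0.16 for Lamtor1, 0.09 for Lamtor2, 0.66 for Lamtor3 and 0.03 for Lamtor4, with adjusted p from 0.0890 to 0.840. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), which is the locus of LysM, had 11356 and 10650 FPKM in knockdown replicates 1 and 2, 73.6 FPKM in knockdown replicate 3, and 29379, 24743 and 22454 FPKM in WT. With this spread within the knockdown its adjusted p was 0.408.

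**Figure D1:**
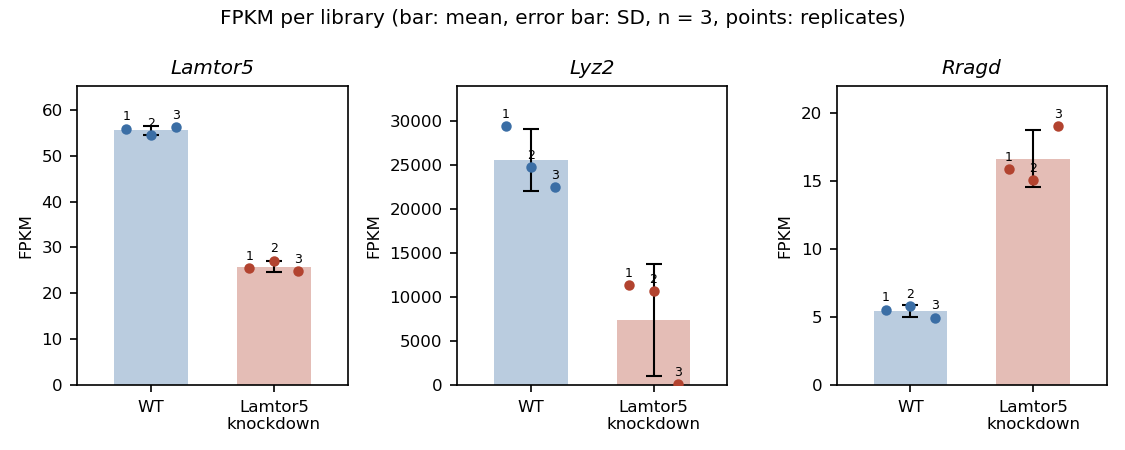
FPKM of Lamtor5, Lyz2 and Rragd in the 3 WT and 3 Lamtor5 knockdown libraries. Bars are means, error bars SD (n = 3) and numbered points single replicates. Lamtor5 lay at 25.8 against 55.5 FPKM, Rragd at 16.6 against 5.43 FPKM, and Lyz2 of knockdown replicate 3 at 73.6 FPKM.

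The comparison of knockdown and WT asks which genes change in macrophages with less Lamtor5; the title of the study names lysosomal activity, the v-ATPase, mTOR signalling and immune homeostasis. The knockdown libraries had more transcripts of a part of the lysosomal and v-ATPase genes, and fewer of most tested cell division genes and of some chemokine and lipid synthesis genes. Of 18164 genes tested with edgeR, 2058 passed an adjusted p of 0.05, 885 higher and 1173 lower in the knockdown, and 900 of them changed at least 2-fold (370 higher, 530 lower). In 6821 genes (37.6%) the groups did not overlap, against 10% by chance, and this held for all 2058 genes that passed. The count depended on single libraries: it was 0 without WT replicate 2 (4065 genes at an unadjusted p under 0.05 in edgeR, 2640 genes by DESeq2 and 0 by limma), 377, 1130 and 781 without knockdown replicates 1, 2 and 3, 2334 without WT replicate 1 and 625 without WT replicate 3. Without WT replicate 2 the smallest adjusted p in edgeR was 0.0616, and 1225 genes had an adjusted p under 0.1. All gene calls below share this dependence on single libraries.

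**Figure D2:**
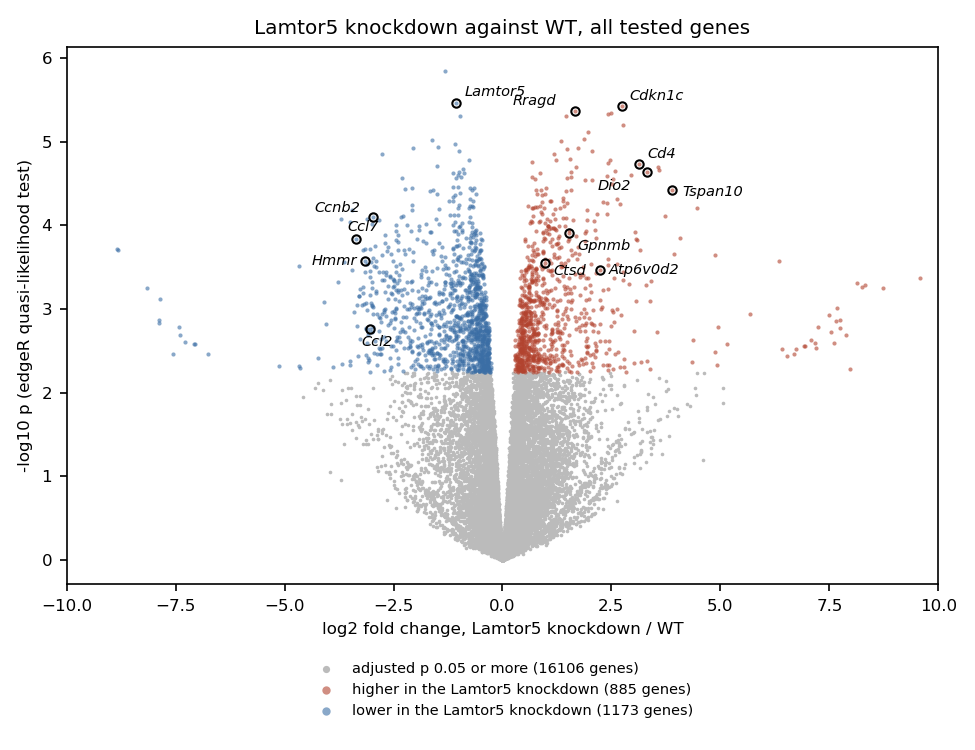
Log2 fold change (Lamtor5 knockdown over WT, x axis) and -log10 of the edgeR p-value (y axis) for 18164 tested genes. Red points are the 885 genes higher and blue points the 1173 genes lower in the knockdown at an adjusted p under 0.05. Circled genes are named in the text, among them Lamtor5 at -1.06 and Rragd at 1.67.

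Some lysosomal acidification genes were higher in the knockdown. Of 20 tested subunits of the v-ATPase, the proton pump of the lysosome, 9 rose and none fell (9 also when adjusted over the list alone), with a list median log2 fold change of 0.24. The increases were mostly modest: Atp6v1g1 rose from 195 ± 3.24 to 302 ± 15.8 FPKM (mean ± SD, n = 3; log2 fold change 0.68, SE 0.069, adjusted p = 0.00963), Atp6v1c1 from 40.6 ± 2.21 to 66.6 ± 6.69 FPKM (0.76, SE 0.097, adjusted p = 0.0114), and Atp6v1d, Atp6v1h, Atp6v1f, Atp6v0d1, Atp6v1e1 and Atp6v1a by 0.41 to 0.64. The exception was Atp6v0d2, a d-subunit isoform found in macrophages and osteoclasts, which rose from 15.5 ± 2.06 to 70.7 ± 34.7 FPKM (2.24, SE 0.34, adjusted p = 0.0152). Camera, a set test that compares a list with all other genes, gave this list an adjusted p of 1.02e-05 with a preset correlation between genes. With an estimated correlation the adjusted p was 0.441, and the self-contained test fry gave an adjusted p of 0.0322. By fry the Ragulator and Rag list also had an adjusted p of 0.0322, and no other fixed list passed.

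Some Rag GTPase, lysosome and autophagy genes were higher too. Of 15 tested Ragulator and Rag GTPase genes 4 rose and 1, Lamtor5 itself, fell (5 and 1 adjusted over the list alone). Rragd, which encodes the Rag GTPase D that pairs with RagA or RagB, rose from 5.43 ± 0.442 to 16.6 ± 2.10 FPKM (log2 fold change 1.67, SE 0.13, adjusted p = 0.00963), and Fnip2 (0.98) and Rragc (0.54) rose as well. Among 48 lysosomal hydrolases 13 rose and none fell (22 and 2 adjusted over the list alone), including the acid alpha-glucosidase gene Gaa (0.96), Pld3 (1.28) and the cathepsin gene Ctsd (0.98). Of 33 genes for lysosomal membrane and trafficking proteins 8 rose and 1 fell (13 and 3 adjusted over the list alone), with the lysosomal calcium channel gene Mcoln1 (0.64) and Cd63 (0.66) higher and the channel gene Tpcn1 (-0.59) lower. Of 31 autophagy genes 9 rose and none fell (12 and 1 adjusted over the list alone), led by Optn (1.39) and Gabarapl1 (0.92). The camera adjusted p was 0.00617 for the Ragulator and Rag list, 8.19e-08 for hydrolases, 0.000864 for membrane proteins and 0.000463 for autophagy. For each of these 4 lists it was 0.441 with an estimated correlation. The Ragulator and Rag call was also lost in limma with quantile normalization, and the other 3 calls with fry. None of the 4 MiT/TFE transcription factors, which drive lysosomal gene transcription, passed at the RNA level. Mitf had a log2 fold change of -0.31 (adjusted p = 0.0604), Tfe3 -0.37, Tfec -0.55 and Tfeb 0.12. Adjusted over the list alone, 0 were higher and 2 lower. The adjusted camera p of the list was 0.23, and 0.555 with an estimated correlation. The activity of these factors was not measured. In the list of the mTOR complexes and their regulators (28 tested) 1 gene rose, the arginine sensor Castor1 (1.01), and 1 fell, Castor2 (-0.52), and 6 rose and 3 fell adjusted over the list alone. Its adjusted camera p was 0.783 (0.918 with an estimated correlation), and the list's median (-0.03) and its test (upward) differed in sign.

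Cell division genes fell together, by more than any other fixed list. Of 34 tested cell cycle genes 26 fell and none rose (33 fell adjusted over the list alone), with a median log2 fold change of -2.42. The mitotic cyclin gene Ccnb2 fell from 37.9 ± 12.2 to 4.67 ± 2.04 FPKM (mean ± SD, n = 3; -2.98, SE 0.36, adjusted p = 0.0113), the kinesin gene Kif20a from 13.6 ± 3.81 to 1.66 ± 0.853 FPKM (-2.99), and the mitotic kinase genes Aurka and Aurkb by -2.44 and -2.32. Each of these genes also climbed from WT replicate 1 to 3: Ccnb2 was at 24.8, 40.2 and 48.8 FPKM and Aurkb at 7.59, 11.5 and 14.9 FPKM. The knockdown libraries lay below all of these, with 3.11 to 6.98 FPKM for Ccnb2 and 1.62 to 2.72 FPKM for Aurkb. The cause of the spread within WT was not tested. The adjusted camera p of the list was 4.43e-36, and 0.441 with an estimated correlation. Among the 12 named genes with the largest decrease, Kif4, Pimreg, Kif18b, Pbk, Prr11, Hmmr, Ccna2, Pclaf, Nuf2 and Ube2c, with log2 fold changes from -3.33 to -3.05, encode proteins of mitosis or DNA replication. On the other side, Cdkn1c, an inhibitor of cyclin-dependent kinases, rose from 17.8 ± 1.16 to 115 ± 34.0 FPKM (2.73, SE 0.21, adjusted p = 0.00963).

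Of the inflammatory and immune signalling genes that passed the test, most were lower. The monocyte chemokine genes Ccl2 and Ccl7 fell from 30.04 ± 18.5 to 3.46 ± 1.72 FPKM (-3.04, SE 0.61, adjusted p = 0.0278) and from 7.14 ± 3.49 to 0.657 ± 0.0935 FPKM (-3.37). Ccl9 (-1.75) and Tnf (-1.38) also fell, whereas Il1a rose from 0.554 ± 0.205 to 4.48 ± 1.48 FPKM (3.06, SE 0.40, adjusted p = 0.0120). In all, 6 of 27 cytokine and chemokine genes fell and 1 rose (7 and 1 adjusted over the list alone). Of 39 Toll-like receptor and NF-kB genes 8 fell and 1 rose (9 and 3 adjusted over the list alone), including the adaptor gene Myd88 (-0.72), Nfkb1 (-0.63), the LPS co-receptor gene Cd14 (-1.22) and Tlr8 (-1.16). Of 35 interferon-stimulated genes 7 fell and none rose (21 and 1 adjusted over the list alone), with Mx2 at -1.96, Cmpk2 at -1.82, Cxcl10 at -2.96 and Ifit1 at -1.47. Their levels were low in both groups: mean FPKM fell from 0.936 to 0.229 for Mx2 and from 2.97 to 0.81 for Cmpk2. For Cxcl10 it fell from 1.53 to 0.183, and for Ifit1 from 6.01 to 2.10. Of 21 immediate early and heat shock genes 9 fell and 1 rose (10 and 2 adjusted over the list alone), with Dusp1 at -1.90, Zfp36 at -1.64 and Ier2 at -1.39. Camera gave an adjusted p of 0.0083 for cytokines, 0.00483 for Toll-like receptors and NF-kB, 2.19e-11 for interferon-stimulated genes and 3.23e-06 for immediate early genes. With an estimated correlation it was 0.441 for each of them, and none passed fry. The immediate early list did not pass in limma with a mean FPKM of at least 5. The cytokine list did not pass camera without knockdown replicate 3 or in any limma fit but the unfiltered one, and the Toll-like receptor list did not pass without WT replicate 1 or in limma with a mean FPKM of at least 5. None of 12 MHC class II genes passed, also adjusted over the list alone (Cd74 had a log2 fold change of -1.23, adjusted p = 0.0583), although the list had an adjusted camera p of 0.0327 (0.555 with an estimated correlation); this call was kept in 12 of 31 settings, and was lost without knockdown replicate 3, without WT replicate 1, with DESeq2, with counts divided by 4, with fry and in every limma fit but the unfiltered one.

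Part of the lipid synthesis genes were lower as well. Of 24 cholesterol synthesis genes 7 fell and none rose (11 fell adjusted over the list alone), such as Fdft1 (-0.68) and Nsdhl (-0.63). Of 13 fatty acid synthesis genes 7 fell and none rose (10 and 1 adjusted over the list alone), such as the desaturase genes Fads2, from 42.4 ± 13.8 to 12.6 ± 5.05 FPKM (-1.71, SE 0.32, adjusted p = 0.0226), and Scd1 (-1.29). By camera the adjusted p was 8.66e-05 for cholesterol and 2.73e-05 for fatty acid synthesis, and 0.441 for both with an estimated correlation. Of 23 genes of the ATF4 and amino acid stress list 2 fell, the serine synthesis gene Psat1 (-2.29) and the amino acid transporter gene Slc38a2 (-0.65), and 1 rose, Atf3 (0.79); the counts adjusted over the list alone were the same. The adjusted camera p was 0.00617 (0.555 with an estimated correlation), and the call was kept in 19 of 31 settings, lost without WT replicate 3, with fry and in 9 limma fits, the one on log2(FPKM + 1) among them. In contrast, 9 of 40 cytosolic ribosomal protein genes rose and none fell (26 rose adjusted over the list alone), by a median of 0.30, with an adjusted camera p of 8.19e-08 (0.448 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, so these values are uncertain where reads were split between copies.

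Macrophage genes moved in both directions. Of 16 macrophage identity genes 7 fell and 1 rose (8 and 2 adjusted over the list alone): the M-CSF receptor gene Csf1r fell from 445 ± 97.2 to 191 ± 31.6 FPKM (-1.18, SE 0.19, adjusted p = 0.0173) and the Fc receptor gene Fcgr1 from 25.3 ± 4.44 to 5.65 ± 2.69 FPKM (-2.11), while the lysosomal marker gene Cd68 rose from 946 ± 21.8 to 1415 ± 149 FPKM (0.63). The adjusted camera p was 0.000558 (0.441 with an estimated correlation), and the call was lost with fry and in limma with a mean FPKM of at least 5. Of 18 lipid-associated macrophage genes 5 rose and 2 fell (6 and 2 adjusted over the list alone). The lists share members, so these counts are not separate from those above. Ctsd and Cd63, which rose here, were already counted as lysosomal genes. Of the identity list, Cd68 was counted with the lysosomal membrane genes and Cd14 with the Toll-like receptor genes. Gpnmb, a lysosomal and melanosomal glycoprotein gene, rose from 1786 ± 34.3 to 4953 ± 1088 FPKM (1.52, SE 0.20, adjusted p = 0.0114), and the lipoprotein lipase gene Lpl fell from 113 ± 37.1 to 20.9 ± 10.6 FPKM (-2.39). This list had an adjusted camera p of 0.00563 (0.441 with an estimated correlation), which was lost without WT replicate 1, with fry and in limma with quantile normalization. Among the 12 named genes with the largest increase were the tetraspanin gene Tspan10 (3.90), the cysteine dioxygenase gene Cdo1 (3.73), the deiodinase gene Dio2 (3.33), Cd4 (3.14), the ubiquitin ligase gene Fbxo32 (2.94), the monoacylglycerol lipase gene Mgll (2.77), Mreg (2.57), the immunoglobulin gene Igha (2.54), Mrgpre (2.49), Htra1 (2.44) and Fstl1 (2.43). Dio2 rose from 15.9 ± 2.01 to 153 ± 68.5 FPKM (SE 0.33, adjusted p = 0.00963).

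**Figure D3:**
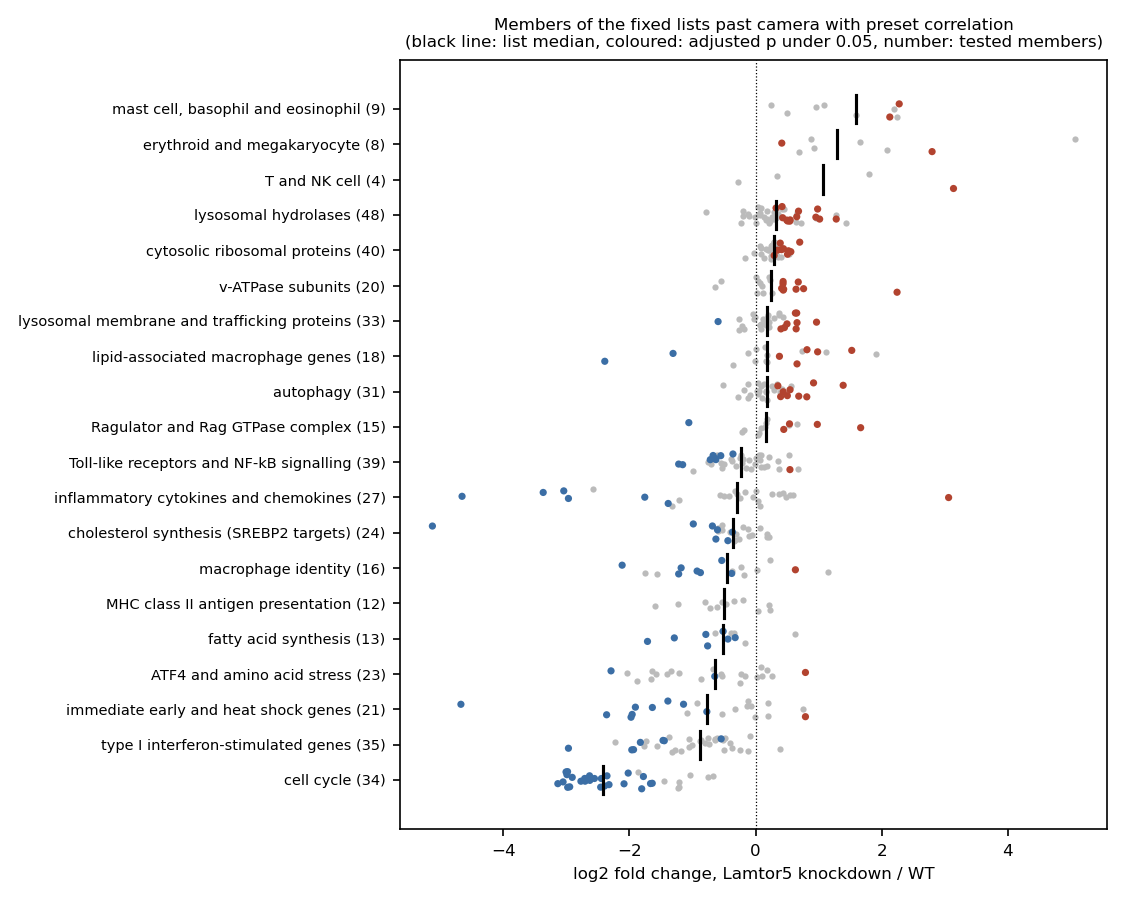
Log2 fold change (x axis, Lamtor5 knockdown over WT) of every tested member of the 20 fixed lists that passed camera with a preset correlation. Each row is a list with its number of tested members, each point a gene, coloured where its adjusted p was under 0.05, and the black line is the list's median. The cell cycle list lay lowest, with a median of -2.42, and the v-ATPase list had a median of 0.24.

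Marker lists of other blood cells were included because bone marrow cultures can hold them, and some moved with the knockdown. Of 9 mast cell, basophil and eosinophil genes 2 rose, Prg2 from 1.07 ± 0.466 to 5.08 ± 1.69 FPKM and Prss34 from 0.947 ± 0.397 to 4.04 ± 1.95 FPKM, and of 8 erythroid and megakaryocyte genes 2 rose, Tfrc (0.42) and Hba-a1 (2.80, a call kept in 6 of 28 settings); none fell in either list (3 and 4 rose adjusted over the list alone). The adjusted camera p was 0.00214 and 0.00418, and 0.441 for both with an estimated correlation; the erythroid and megakaryocyte call was also lost in limma with a mean FPKM of at least 5. The T and NK cell list passed camera (adjusted p = 0.0212, and 0.441 with an estimated correlation) on 4 tested genes of 13, of which Cd4 alone rose, and was kept in 10 of 18 settings, lost among others without WT replicate 2, without knockdown replicates 1 or 3 and without a filter on low counts. Cd3d, Cd3e and Cd3g, the T cell receptor partners, were under the count filter in all libraries. In the neutrophil list Ltf (-1.76) fell and Mpo (0.95) rose, in the dendritic cell list Kit (2.23) rose, in the B cell list Ighm (-1.74) fell, in the monocyte list Ccr2 (-2.08) fell, in the osteoclast list Itgb3 (1.74) and Atp6v0d2 rose, and in the endothelial list Kdr (1.06) rose. Of the 9 tested B cell genes 7 were below 0 and 2 above. The immunoglobulin gene Igha, which the B cell list lacks, rose from 5.18 ± 1.41 to 28.7 ± 14.8 FPKM. None of 13 fibroblast genes passed. Adjusted over the list alone, 2 neutrophil genes rose and 1 fell, 2 dendritic cell genes rose, 1 B cell gene fell, 2 monocyte genes fell, 2 osteoclast genes rose and 1 fell, and 2 endothelial genes rose. For these 7 lists camera gave adjusted p from 0.0541 to 0.858, and 0.441 to 0.918 with an estimated correlation.

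The remaining fixed lists did not pass camera, with adjusted p from 0.119 to 0.907 (0.555 to 0.955 with an estimated correlation). In the list of alternative activation Cd163 (-1.45, from a mean of 1.22 to 0.433 FPKM) and Stab1 (-2.23) fell, and Clec7a (2.002) and Tgm2 (0.49) rose. In the list of phagocytic, Fc and complement receptors (22 tested) 6 genes fell, among them C3ar1 (-1.06), and 3 rose; its median was 0.15 and its mean -0.27. Of 11 complement genes 4 fell, among them C1qb (-1.73), and C2 (2.12, from a mean of 0.175 to 0.736 FPKM, a call kept in 7 of 16 settings) rose. Of the 16 MHC class I genes B2m (0.67) and H2-D1 (0.77) rose and Psmb10 (-0.82) fell; H2-D1 shares reads with other class I genes, so its value is uncertain. Of 21 glycolysis genes Eno2 (1.69) rose, and Pfkp (-0.60), Hif1a (-0.40) and Slc2a1 (-0.41) fell. In the NRF2 list Osgin1 (1.27) rose, and Me1 (-0.79) and Tkt (-0.45) fell. Calr (0.34) and Dnajb9 (0.44) of the unfolded protein response list and Ndufa1 (0.45) and Ndufb5 (0.35, a call kept in 8 of 29 settings) of the 36 oxidative phosphorylation genes rose. Adjusted over the list alone, the numbers higher and lower were 2 and 3 for alternative activation, 5 and 8 for phagocytic receptors, 2 and 5 for complement, 4 and 3 for MHC class I, 1 and 3 for glycolysis, 1 and 3 for NRF2, 2 and 0 for the unfolded protein response and 1 and 0 for oxidative phosphorylation. Camera pointed against the median in the glycolysis, phagocytic receptor, dendritic cell and osteoclast lists, and against the mean in the glycolysis, dendritic cell and endothelial lists.

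Library values were compared between the groups with an exact permutation test, whose smallest p is 0.1 with 3 against 3. The 10 most abundant genes took 17.6 ± 1.46% of the counts in the knockdown and 14.7 ± 0.553% in WT (mean ± SD, n = 3; exact permutation test, two-sided, p = 0.1, Benjamini-Hochberg adjusted p = 0.14 over 7 measures), and mitochondrial genes 2.86 ± 0.155% and 2.39 ± 0.112% (exact p = 0.1, adjusted p = 0.14). Total counts were 78.9 ± 2.83 and 82.9 ± 0.361 M (exact p = 0.1, adjusted p = 0.14). The share of first reads with adapter sequence was 8.72%, 15.02% and 12.3% in the knockdown libraries and 8.91%, 8.70% and 8.14% in WT (exact p = 0.2, adjusted p = 0.233).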

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

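The fits on counts divided by 4, with length and GC offsets, with robust estimation and with the bias-adjusted edgeR fit, and DESeq2 and limma with a library left out, were chosen after seeing the data. The count of 2058 changed genes was 4167 with DESeq2, 5446 with limma and array weights (whose weight estimation stopped before converging), 1205 in edgeR and 789 in limma without a filter on low values (more genes are then tested), 900 with at least a 2-fold change and 3835 at an adjusted p under 0.1. Leaving out a library gave 0 to 2334 genes: 0 without WT replicate 2 (2640 by DESeq2, 0 by limma), 377, 1130 and 781 without knockdown replicates 1 to 3, and 625 without WT replicate 3. The other fits gave 1521 to 2409, apart from those with a replicate block. The cause of these changes was not tested. Lamtor5 kept its call and direction in all fits except without WT replicate 2; its log2 fold change ranged from -1.09 to -1.04 with a library left out. Of 129 named genes that passed, 34 lost the call only without WT replicate 2, and none changed sign in any fit. Camera called 20 lists, 11 with a mean FPKM of at least 5 (fewer genes tested), 0 with an estimated correlation, 2 by fry and 14 to 24 otherwise; no called list changed direction. Scaling moved limma's split: 743 higher and 1231 lower on deposited FPKM, 978 and 996 with upper-quartile scaling. The labels do not say whether libraries with the same replicate number share a litter, batch or day. Deviations from the group means correlated at 0.05, 0.04 and -0.01 for numbers 1 to 3, and knockdown replicate 3 correlated best with another number. These small values gave no sign of pairing but cannot exclude it. With a replicate block edgeR called 659 genes (728 with RLE factors) and limma 472 (474 with median-of-ratios scaling). In the simulation with 3 libraries per group, 2 of 67 genes changed 1.5-fold were recovered, with 55 calls in all against 2058 here. The adjusted p depends on how many genes change, so this share cannot say what the real comparison could detect. Some called genes changed by less than 1.5-fold, such as Atp6v1a (1.33-fold) and Calr (1.27-fold).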

Other observations

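The pathway tests, and the tests of a wrong label, of fewer macrophages, of Lyz2 alleles, of a few abundant genes, of progenitor cells and of other splits, were chosen after the results were seen. Pathways from the table's own KEGG annotation added some gene groups that the fixed lists lack. Of 302 pathways with 10 to 300 tested genes, 38 passed camera with a preset correlation (9 up, 29 down), and none with an estimated correlation. The smallest p-values were those of cell cycle (5 higher and 31 lower of 120, adjusted p = 1.3e-07) and DNA replication (1 and 11 of 35, adjusted p = 1.79e-06). With an estimated correlation these adjusted p-values were 0.547 and 0.594. Whether DNA repair pathways fell apart from these 2 was not tested. Of the DNA repair pathways, 13 of 40 homologous recombination genes and 12 of 52 Fanconi anemia genes fell and none rose (adjusted p = 6.79e-06 each, 0.547 and 0.548 with an estimated correlation), and in mismatch repair 6 of 23 fell and 1 rose (adjusted p = 0.00188, and 0.686 with an estimated correlation). Base excision repair (2 higher and 5 lower of 34, adjusted p = 0.0508), nucleotide excision repair (3 and 5 of 43, adjusted p = 0.222) and non-homologous end-joining (1 and 1 of 12, adjusted p = 0.533) did not pass. In the cytochrome P450 drug metabolism pathway 9 of 38 genes rose and none fell (adjusted p = 0.000443, and 0.536 with an estimated correlation). The number of pathways past the test ranged from 16 (limma, mean FPKM at least 5) to 79 (limma without a filter).

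Igf1, singled out after its value was seen, fell from 30.4 ± 1.98 to 11.8 ± 0.536 FPKM (log2 fold change -1.31, SE 0.085, edgeR adjusted p = 0.00963), with all 3 knockdown libraries below all 3 WT libraries. Xist, expressed from the inactive X chromosome, had 23.7 to 38.4 FPKM in the 6 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 22 estimated counts in any of them.

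Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, gave as many genes as the 2058 reported, and the highest of the others gave 2. With 10 splits the share cannot fall below 0.1. Each other split puts knockdown and WT libraries in the same group, so the difference between the genotypes adds to the spread within its groups. Their low numbers are therefore no measure of what chance would give.

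Lyz2 was at 44.5% and 41.7% of the WT mean in knockdown replicates 1 and 2 and at 0.288% in replicate 3. A wrong label is argued against, since Lamtor5 in replicate 3 was at 44.6% of the WT mean, and so are reads assigned to the paralog Lyz1, since the sum of both lysozyme genes there was 0.972% of that in replicates 1 and 2. Fewer macrophages would lower other identity genes too, but the median of 14 such genes in replicate 3 differed from replicates 1 and 2 by -0.27 on the log2(FPKM + 1) scale (lowest -1.09). A candidate explanation is the number of Lyz2 alleles that carry a Cre insertion, 1 in replicates 1 and 2, both in replicate 3 and none in WT, but the genotypes were not analysed here and it stays open. If so, knockdown and WT would also differ in Cre and in lysozyme, which these libraries cannot separate from Lamtor5.

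The higher level of v-ATPase and lysosomal hydrolase genes was weighed against technical causes. With offsets for transcript length and GC content per library, the 22 called members had a median log2 fold change of 0.55, as without offsets (0.55). Over all tested members the median was 0.27 for the v-ATPase (0.24 without offsets) and 0.30 for hydrolases (0.32 without). Both lists passed camera with offsets (adjusted p = 4.03e-05 and 2.82e-07). A few genes taking a larger share of the counts would move all genes alike. The smaller of the list medians without offsets lay 0.22 above the median of all tested genes. This restates the camera result, so it is no separate test. A biological effect of genotype is thus a hypothesis that stays open, beside the difference at Lyz2. The loss of gene calls without WT replicate 2 limits it. Camera with an estimated correlation gave both lists an adjusted p of 0.441 and called none of the 37 lists. The cell cycle list (estimated correlation 0.93) and the Ragulator and Rag list (-0.005) had the same value. It thus lends these lists no support, but cannot tell lists whose genes vary together from others.

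The lower level of cell cycle genes was not explained by transcript length and GC content: with offsets the list median was -2.39 (-2.42 without). Cycling myeloid progenitor cells left in the WT cultures stay open. They would put progenitor markers lower in the knockdown, and the 10 markers had a median log2 fold change of 0.95 (quartiles 0.19 and 1.17), which lies above 0 by less than the distance between the quartiles (0.98). Of the 10 markers 9 were above 0: Mpo and Kit passed as higher, and Elane (1.195, adjusted p = 0.135) and Prtn3 (1.24, adjusted p = 0.0571), which go against the explanation, did not pass. Cd34 was below 0 (-1.02, adjusted p = 0.194), with at most 1.48 FPKM in any library, and Myb, Gfi1, Ms4a3 and Fcnb had at most 0.640 FPKM. Of 10 monocyte genes 1, Ccr2 (-2.08), fell and 4 were above 0; the list median was -0.75 (-0.92 to 0.14 across settings) and the camera adjusted p 0.0755. A difference in the division of the macrophages themselves, through genotype, culture density or timing, may equally remain; the density and timing of the cultures were not analysed here.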
